A study of Mus musculus with 3 samples.

How the data were processed

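Single-cell RNA sequencing libraries of day 7 fracture callus from female C3H/HeJ mice were taken from 3 groups (vehicle control, PTH and YKL), with 1 library per group. Cells had been released with collagenase, marrow was avoided, and droplet libraries were made with a 3′ kit that counts unique molecular identifiers (UMIs). The deposited matrices hold raw UMI counts per gene and barcode, made with Cell Ranger 4.0.0 per the file headers. The processing notes name Seurat and the mouse build mm10 as well, and give no filter on cells. The lowest total of a barcode was 500 UMIs in each library. Each matrix had 32285 gene rows, of which 78 shared a symbol with another row and were kept apart by identifier. Items that the labels list beyond these matrices were not used here.

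Cells with at least 500 detected genes and at most 10% mitochondrial UMIs were kept. Scrublet, run in each library, marked 46 of 4918 control, 1 of 4301 PTH and 3 of 1041 YKL barcodes at automatic thresholds of 0.253, 0.507 and 0.268. These shares are too low for droplet runs of this size, so the caller failed and most doublets are taken to remain. The marked barcodes lay mostly in the control library, so their removal was uneven between libraries. Kept cells were scaled to 10000 UMIs, 2000 variable genes were chosen within libraries, and 30 principal components and 15 neighbours fed Leiden clustering at resolution 0.8, without integration between libraries. Clusters were named from marker sets of 18 cell classes by folds over the median CPM of the clusters, with 10 CPM added. A marker counted where it was detected in a share of at least 0.1 of cells, and a leading gene in at least 0.25. A cluster stayed unnamed when markers of another class were in greater number among its leading or detected genes, or when haemoglobin passed 10% of its UMIs. It also stayed unnamed, as tendon-led, when the tendon gene Tnmd was among its first leading genes, since no marker set covers tendon.

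For each class with at least 50 cells in both libraries, UMIs were summed over cells and given as CPM, the usual scaling of counts to the class total. Class totals of chondrocytes were 25934655 UMIs in the control, 13288966 in the PTH and 13350867 in the YKL library, and those of endothelial cells 1163968, 2288214 and 533085. Fibroblast-like cells held 1224156 control and 3353633 PTH UMIs, macrophage-like cells 1215324 and 1045377, and osteoblast-lineage cells 556567 and 1140458. Ratios were computed for genes with at least 50 UMIs over both libraries. Their 95% intervals are exact conditional binomial intervals, and shares carry exact Clopper-Pearson intervals. UMIs from 1 library are not biological replicates, so intervals and floors cover counting error only and no test between groups was run. A gene at 0 UMIs was held at a floor of 3 counts, in list medians and list counts too.

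Before the data were examined, 26 gene lists were fixed for this tissue and treatment (490 symbols with the markers, 4 of which match no gene row). They include mineralization, kinase pathway, cAMP and CRTC response, signalling, stress, cell cycle and immune lists, and markers of free RNA. For each list the members at least 1.5-fold higher or lower were counted and the median log2 ratio was set against 10000 random lists matched in level. The cAMP and dissociation lists share 4 genes, and the hypertrophic and osteoblast lists share 3. Also fixed in advance were 18 genes to report in chondrocytes. The rule for named genes took, per class and comparison, the 3 genes higher and the 3 lower whose interval bound nearest to 1 was farthest from it, among genes of at least 50 CPM in 1 of the libraries. It left out mitochondrial and ribosomal protein genes, predicted genes and markers of other classes, and up to 4 members were named for each list described. Chondrocytes and endothelial cells alone had 50 cells in each library. Naming genes in osteoblasts, fibroblasts and macrophages, and for YKL against PTH, was chosen after cell counts had been seen.

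The 3 comparisons were PTH against control, YKL against control and YKL against PTH. Similarity of the treatments was measured across genes as correlation and covariance of log2 ratios, beside 100 simulated pairs of libraries drawn from the control without change. Shares of cells with a UMI were taken after each cell was thinned to 2000 UMIs. Chondrocytes were also clustered without the 38 hypertrophic, bone matrix and mineralization genes. The new clusters of at least 5000 CPM Col10a1 over all libraries together were counted. The code was tested on simulated data. In simulated chondrocytes 95.4% (PTH against control) and 96.2% (YKL against control) of unchanged genes had intervals that covered 1, and 0.932% and 0.595% passed 1.5-fold. A 15-gene list raised 2-fold returned medians of 1.01 and 0.98.

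Set at the same time as the lists were 58 alternatives of 17 kinds. They changed the minimum of genes to 200 or 1000, the mitochondrial maximum to 5% or 20%, the resolution to 0.4 or 1.6, the variable genes to 4000 and the UMI minimum to 10 or 200. Others clustered each library alone, took classes from marker scores, kept doublets, averaged CPM over cells, thinned cells, scaled by median ratios, left haemoglobin, granule and mitochondrial genes out of the totals, or left markers out of the similarity. After the data were seen, 20 of 6 kinds were added: chondrocyte clusters weighted equally (those with at least 10 cells in each library), cells of 10000 to 20000 UMIs, a doublet score limit of 0.25, mixed clusters kept, the tendon-led cluster counted with fibroblasts, and the cAMP list without dissociation genes. In every comparison the equal weighting leaves out the cycling chondrocyte cluster 14, which held 1 YKL cell.

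Gene positions came from the GENCODE M21 annotation of GRCm38, in which 32158 of 32285 rows (99.6%) were found by identifier. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, scikit-image 0.26.0 and matplotlib 3.10.9, with a random seed of 1.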

Results

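Fracture callus was collected on day 7 after a pinned midshaft fracture of the femur in female C3H/HeJ mice and profiled by droplet single-cell RNA sequencing. Mice had received vehicle, an N-terminal fragment of parathyroid hormone (PTH) at 100 µg/kg, or the kinase inhibitor YKL-05-099 (YKL) at 15 mg/kg, each by injection under the skin once a day. YKL-05-099 inhibits the salt-inducible kinases, which act below the PTH receptor and hold back CRTC coactivators and class IIa histone deacetylases. The question of the series is whether inhibitors of these kinases stimulate mineralization of a fracture, with PTH as the established bone-forming treatment. There were 3 libraries, 1 per group. The control library held 55250651 UMIs in 8021 barcodes, the PTH library 33981167 in 5286 and the YKL library 19424073 in 1500. Filtering kept 2907, 1912 and 604 cells, with a median of 11633, 12290.5 and 25867.5 UMIs per cell. With 1 library per group no test was possible and no difference had a replicate check, so each comparison describes these libraries and every interval (95%) covers counting error only.

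Cartilage cells were the largest class in each library. Chondrocyte-like cells made up 53.7% (95% interval 51.9 to 55.6) of the control cells, 37.8% (35.6 to 40.0) of the PTH cells and 70.9% (67.1 to 74.5) of the YKL cells. Endothelial-like cells, the lining of blood vessels, took a higher share of the PTH library (14.9%, 13.3 to 16.6) than of the YKL (8.44%, 6.35 to 11) and control libraries (5.44%, 4.64 to 6.32). Fibroblast-like or mesenchymal progenitor-like cells made up 15.2% (13.6 to 16.9) of the PTH cells against 3.99% (3.31 to 4.77) of the control and 3.15% (1.90 to 4.87) of the YKL cells. Osteoblast-lineage-like cells were few, at 50 of 2907 control cells, 62 of 1912 PTH cells and 19 of 604 YKL cells. Neutrophil-like cells stood at 14.8% (13.5 to 16.1) in the control library, 1.10% (0.681 to 1.67) in the PTH library and 2.65% (1.52 to 4.27) in the YKL library. Macrophage-like or monocyte-like cells took 4.4%, 4.08% and 2.81% in the same order, pericyte-like or smooth muscle-like cells 2.68%, 3.24% and 1.32%, T-like or NK-like cells 2.72%, 0.523% and 1.32%, and Schwann-like or glial-like cells 0.722%, 1.88% and 0.166%. Unnamed clusters held 9.84%, 18% and 6.13%. A tendon-led unnamed cluster (Thbs4, Tnmd, Abi3bp, Kera) accounted for 240 of the 1912 PTH cells, 2 of the 2907 control cells and 0 of the 604 YKL cells, which allows up to 0.497% by a floor of 3 cells (exact upper bound 0.609%). Marrow had been avoided at dissection and the filters removed more barcodes with a high mitochondrial share from the PTH library (44.5% of barcodes) than from the control (17.6%) and YKL (18.5%) libraries. Among barcodes with at least 500 genes it was 21.5% in the PTH, 14.3% in the control and 11.8% in the YKL library. All shares count captured cells that passed the filters.

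**Figure D1:**
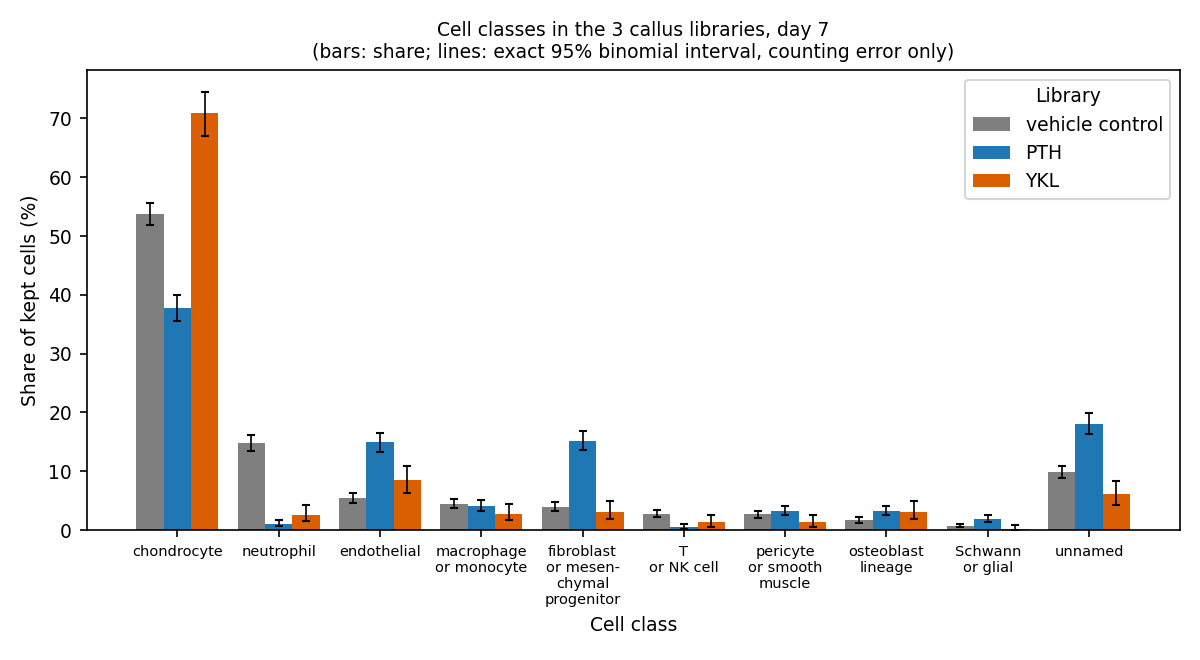
Share of kept cells in each cell class (y axis, percent) in the vehicle control, PTH and YKL libraries; bars are shares and lines exact 95% binomial intervals for counting error only. Chondrocytes took 53.7%, 37.8% and 70.9% of the control, PTH and YKL cells.

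The inhibitor was first set against vehicle in chondrocytes. All 11 measured genes of hypertrophic cartilage, the stage at which chondrocytes enlarge and their matrix calcifies, were at least 1.5-fold higher in the YKL library, with a median log2 ratio of 1.22. Col10a1, the collagen of hypertrophic cartilage, was 3.09-fold higher (95% interval 3.06 to 3.11), at 2964 normalised counts (CPM) in the control and 9148 CPM in the YKL chondrocytes. Ihh, the hedgehog ligand of prehypertrophic chondrocytes, was 3.38-fold higher (3.26 to 3.52), and Mmp13, a collagenase of late hypertrophic cartilage, 3.45-fold higher (3.29 to 3.62). Of 18 measured osteoblast and bone matrix genes, 12 were at least 1.5-fold higher and 1 lower, with a median of 0.97 (0.37 in thinned cells). Bglap, which encodes osteocalcin, was 13.6-fold higher (11.2 to 16.6), and Dmp1, Ifitm5 and Bglap2, genes of mineralizing bone cells, were 35.5-fold (17.5 to 83.7), 38.1-fold (18.9 to 89.9) and 39.4-fold (18.6 to 99.8) higher. Such ratios can depend on how the classes are cut. In YKL against PTH, Dmp1 was at 0.172 with doublets kept or a minimum of 1000 genes, settings that gave no osteoblast class. Cluster 6, led by Col10a1, Ibsp and Ihh, held 52.3% of the YKL and 13.9% of the control chondrocytes. Clusters 1 and 2, led by Ucma and Cnmd, held 9.81% and 7.01% of the YKL and 25.9% and 32.8% of the control chondrocytes. Cluster 0, led by Col9a3, held 22.0% of both. When chondrocyte clusters were weighted equally the hypertrophic median was 0.31, 3 of 11 genes were at least 1.5-fold higher, and the ratios of Col10a1, Ihh and Bglap were 0.833, 1.24 and 5.86. Within cluster 6 the median was −0.02, and with a mitochondrial maximum of 5% the ratio of Ifitm5 was 2.47.

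Since those genes define cluster 6, the chondrocytes were clustered again without the 38 hypertrophic, bone matrix and mineralization genes. New clusters with Col10a1 at 5000 CPM or more then held 72.9% (68.4 to 77.1) of the 428 YKL chondrocytes, 31.5% (28.2 to 35.1) of the 723 PTH chondrocytes and 17.7% (15.8 to 19.7) of the 1562 control chondrocytes. They were picked by their Col10a1 level over all 3 libraries together, so that gene still entered the choice. New cluster 8, among those picked, held 16.8% of the YKL and 2.11% of the control chondrocytes. Within it Col10a1 was at 0.161 (0.157 to 0.165) in YKL against control. With each cell thinned to 2000 UMIs, Col10a1 was detected in 71.6% of the YKL, 34.2% of the PTH and 30.8% of the control chondrocytes. The unthinned shares were 96.5%, 57.8% and 65.6% at median depths of 29961, 17730 and 16363.5 UMIs, and 13, 19 and 29 chondrocytes were too shallow to thin. Endothelial cells, which should lack Col10a1, had a UMI in 34.0%, 5.53% and 11.3% of thinned cells in the same order, at median depths of 7799, 6062 and 5512 UMIs. Thinned Ihh, in turn, was seen in 42.4%, 21.7% and 15.2% of chondrocytes (70.6%, 37.8% and 29.1% unthinned) and in 0 of 47, 3 of 253 and 0 of 142 endothelial cells. A floor of 3 cells allows up to 6.38% of 47 and 2.11% of 142 cells (exact upper bounds 7.55% and 2.56%) with a UMI at this depth, not cells expressing it. Unthinned shares were 3.92%, 1.40% and 2.53%.

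**Figure D2:**
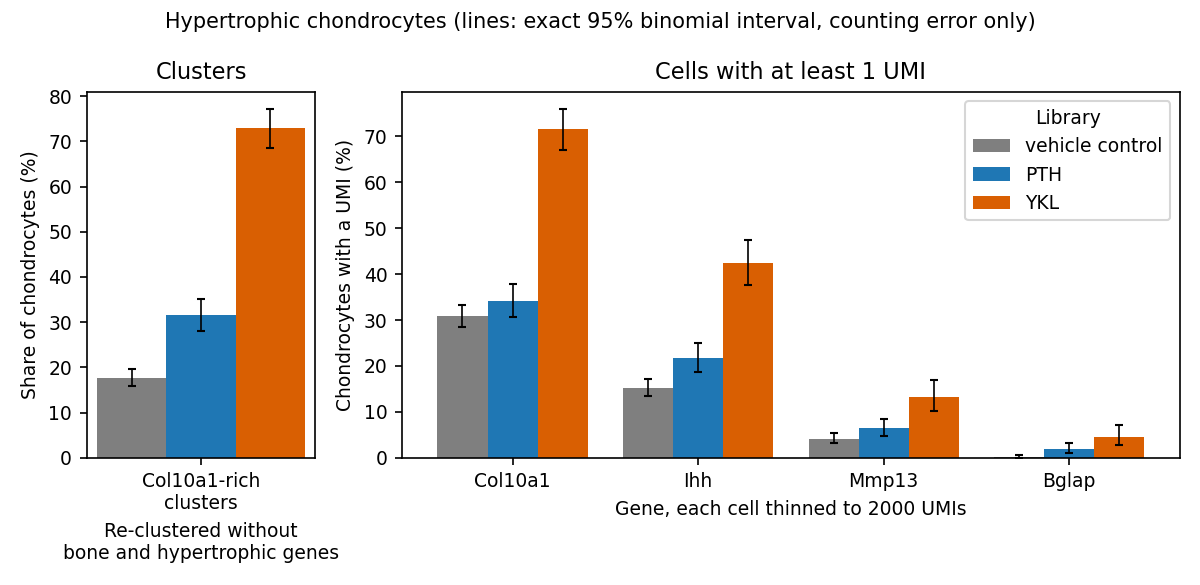
Left, share of chondrocytes (percent) in Col10a1-rich clusters formed without bone and hypertrophic genes and picked by Col10a1 over the libraries together. Right, share of chondrocytes (percent) with at least 1 UMI of Col10a1, Ihh, Mmp13 or Bglap after thinning to 2000 UMIs. Bars are the control, PTH and YKL libraries and lines exact 95% binomial intervals; the Col10a1-rich share was 17.7%, 31.5% and 72.9%.

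Targets and pathway genes were measured in the same cells. Of 21 measured genes that respond to cAMP, CREB and CRTC, 13 were at least 1.5-fold higher in the YKL chondrocytes and none was that much lower, with a median of 0.68. The orphan nuclear receptor genes Nr4a1 and Nr4a3 were 2.19-fold (1.99 to 2.42) and 2.55-fold (2.0 to 3.26) higher, the immediate early gene Atf3 2.65-fold (2.49 to 2.82) and the phosphatase gene Dusp1 2.12-fold (2.02 to 2.21). Within cluster 6 alone the count was 11 of 19 with a median of 0.71, and Nr4a1 was 5.35-fold higher (3.72 to 7.95). Genes that tissue digestion and heat shock induce were also higher, 7 of 16 at least 1.5-fold with a median of 0.50, and 4 genes belong to both lists; without them the cAMP median was 0.59. Among the kinases themselves, Sik1 was 2.05-fold higher (1.40 to 3.0) from 56 control and 59 YKL UMIs, Sik2 1.23-fold (0.927 to 1.62) and Sik3 1.32-fold (1.15 to 1.5). Of the 16 measured components of the kinase pathway 5 were at least 1.5-fold higher (median 0.29), among them the receptor gene Pth1r at 1.81-fold (1.78 to 1.85) and the transcription factor genes Mef2c at 1.97-fold (1.92 to 2.01) and Mef2a at 1.82-fold (1.68 to 1.962). The mineralization list had 7 of 14 genes at least 1.5-fold higher and a median of 0.54, with alkaline phosphatase (Alpl) at 2.33-fold (2.29 to 2.38), osteopontin (Spp1) at 2.35-fold (2.32 to 2.38) and the phosphatase gene Phospho1 at 2.75-fold (1.58 to 4.85). Ibsp, bone sialoprotein, was 2.44-fold higher (2.42 to 2.47). Of the other genes fixed in advance, the osteoblast transcription factor genes Runx2 and Sp7 were at 1.6 (1.5 to 1.72) and 1.29 (1.18 to 1.40), Fos at 1.6 (1.57 to 1.63), Col1a1 at 1.43 (1.41 to 1.44), Acan at 1.16, Sox9 at 1.02 and Tnfsf11, the osteoclast-inducing ligand RANKL, at 0.809 (0.529 to 1.21). Under the equal weighting of chondrocyte clusters, the mineralization median was 0.13, and the ratios of Ibsp, Spp1 and Mmp13 were 0.901, 0.902 and 0.923.

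Genes of proliferation and of insulin-like growth factor signalling were lower in the YKL chondrocytes. All 20 measured G2 and M phase genes were at least 1.5-fold lower (median −2.48), including the proliferation marker Mki67 at a ratio of 0.0660 (0.0326 to 0.120) and topoisomerase Top2a at 0.130 (0.0909 to 0.182). The cycling cluster 14 held 20 of 1562 control (1.28%, 0.784 to 1.97) and 1 of 428 YKL chondrocytes (0.234%, 0.00592 to 1.29). Thinned Mki67 was seen in 1.11% (0.647 to 1.77) and 0.241% (0.0061 to 1.34) of them. These intervals of cells overlap, and the intervals of the ratios count UMIs and not cells. With clusters weighted equally, which leaves out cluster 14, 3 of 7 G2 and M phase genes were lower (median −0.57). Insulin-like growth factor genes were lower too, 6 of 10 at least 1.5-fold with a median of −0.95, with Igf1 at 0.372 (0.319 to 0.431) and Igf2 at 0.394 (0.354 to 0.438). The cartilage matrix list had a median of −0.12, and 4 of 18 members were at least 1.5-fold lower, among them Epyc at 0.553 (0.520 to 0.588) and Matn3 at 0.632 (0.623 to 0.643), while Col2a1, the main collagen of cartilage, was at 1.16 (1.16 to 1.17). By the naming rule, the genes that stood lowest were Tnmd (tenomodulin) at 0.0114 (0.00491 to 0.0225), Ucma, a secreted cartilage protein that leads cluster 1, at 0.127 (0.123 to 0.132) and Aspn (asporin) at 0.175 (0.159 to 0.192). The highest were Depp1 at 4.47 (4.11 to 4.85), Irx5 at 4.03 (3.68 to 4.4) and Dhx58os at 4.03 (3.73 to 4.35), the last uncertain because it is antisense to Dhx58 and the handling of strand is not given in the sources used here. With clusters weighted equally, Depp1 was at 1.27 and Irx5 at 1.17.

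Signalling lists in the YKL chondrocytes went both ways. In the BMP and TGF-beta list 10 of 21 genes were at least 1.5-fold higher and 3 lower (median 0.05), with the ligand gene Bmp2 at 3.27 (2.88 to 3.71), its antagonist Nog at 2.91 (2.69 to 3.16) and the antagonist Grem1 at 0.232 (0.148 to 0.349). Among 16 WNT genes 4 were higher and 6 lower (median 0.15), with the feedback gene Axin2 at 3.60 (2.49 to 5.24) and the secreted antagonist Sfrp2 at 0.234 (0.139 to 0.373). For hypoxia and glycolysis 3 of 19 were higher, among them Vegfa, the vascular growth factor, at 1.97 (1.86 to 2.07), and the median was −0.14. Markers of other cells also differed between these chondrocytes: haemoglobin genes had a median of −0.57 (−2.78 by marker scores), neutrophil granule genes −3.97 and MHC class II genes −2.46, and mitochondrially encoded genes −0.44. Fibroblast markers were at least 1.5-fold lower in 7 of 12 (median −0.72), skeletal muscle markers in 5 of 5 (−2.14) and endothelial markers in 2 of 3 (−1.30). Pericyte markers had a median of 0.09 and Schwann-like markers −0.09.

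PTH was set against vehicle in the same class, as the reference treatment. In the PTH chondrocytes 4 of 14 measured osteoblast genes were at least 1.5-fold higher and none lower, with a median of 0.43. Bglap was 4.47-fold higher (3.58 to 5.59), Ibsp 2.19-fold (2.17 to 2.22), the keratan sulphate proteoglycan gene Omd 1.78-fold (1.73 to 1.82) and the type I collagen gene Col1a1 1.47-fold (1.45 to 1.48). The hypertrophic list had 2 of 11 members at least 1.5-fold higher (median 0.25); Ihh was 1.72-fold higher (1.65 to 1.80), while Col10a1 was at 1.04 (1.02 to 1.05) and Mmp13 at 0.960 (0.898 to 1.03). Mineralization genes had a median of 0.31 with 1 of 12 past 1.5-fold, the phosphate transporter gene Slc20a1 at 1.84 (1.54 to 2.21). Most PTH chondrocytes lay in clusters 2, 1 and 6 (25.6%, 23.1% and 21.9%), and most control chondrocytes in clusters 2, 1 and 0. The count of osteoblast genes was 2 of 15 with clusters weighted equally and 11 of 18 with a mitochondrial maximum of 5%. Under equal weights the mineralization median was 0.02 and the hypertrophic median −0.01, with Ihh at 1.04 and Col10a1 at 0.555.

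Of 21 cAMP, CREB and CRTC genes 7 were at least 1.5-fold higher and 1 lower in the PTH chondrocytes, with a median of 0.33, among them the immediate early genes Fos at 1.61 (1.58 to 1.63) and Atf3 at 1.70 (1.58 to 1.82) and Sik1 at 1.57 (1.04 to 2.36). With a mitochondrial maximum of 5% the count was 3 of 21. Tnfsf11, an established PTH target in bone cells, was lower at 0.325 (0.171 to 0.577) from 14 PTH and 84 control UMIs. Dissociation and heat shock genes had a median of 0.36 with 4 of 16 higher, and without the shared members the cAMP median was 0.18 and 4 of 17 genes were past 1.5-fold. Sik2 was at 1.21 (0.907 to 1.59), Sik3 at 1.16 (1.02 to 1.33) and Pth1r at 1.14 (1.12 to 1.16), and the kinase pathway list had 2 of 16 genes past 1.5-fold and a median of 0.20. G2 and M phase genes were higher, 10 of 20 at least 1.5-fold with a median of 0.55 and Top2a at 1.87 (1.66 to 2.11). The median was −0.58 with chondrocyte clusters weighted equally, which leaves out the cycling cluster 14. That cluster held 14 of 723 PTH (1.94%, 1.06 to 3.23) and 20 of 1562 control chondrocytes (1.28%, 0.784 to 1.97). Runx2 was at 1.29 (1.19 to 1.38), Alpl at 1.32 (1.29 to 1.36), Nr4a1 at 1.26 (1.12 to 1.41; 0.833 in thinned cells), Sp7 at 1.04 (0.944 to 1.14), Acan at 1.11, Col2a1 at 1.01 and Sox9 at 0.937. Of 19 hypoxia and glycolysis genes 0 were past 1.5-fold, with a median of −0.32 and lactate dehydrogenase Ldha at 0.716 (0.704 to 0.728), and in cluster 6 the median was 0.51.

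By the naming rule the genes that stood highest in the PTH chondrocytes included Thbs4, a thrombospondin of tendon, at 4.02 (3.53 to 4.58) and the secreted WNT antagonist gene Sfrp5 at 3.54 (3.18 to 3.94). Thbs4 was also counted in endothelial cells of the PTH library, at 15.7 CPM against 53.3 CPM in its chondrocytes. In the clustering without bone genes, new clusters 2 and 10, led by Tnmd and Sfrp5, held 21.4% and 20.5% of the PTH, 6.47% and 1.28% of the control and 0.467% and 0.701% of the YKL chondrocytes. The lowest were the TGF-beta-induced matrix gene Tgfbi at 0.297 (0.275 to 0.321), Ptx3, a pentraxin, at 0.376 (0.338 to 0.417) and Pcp4 at 0.380 (0.335 to 0.430). WNT genes had 6 of 16 members higher and none lower (median 0.25; Notum 1.93, 1.53 to 2.43), BMP and TGF-beta genes 5 higher and 2 lower of 21 (median 0.26; Grem1 3.19, 2.69 to 3.79), and IGF genes 2 higher of 10 (median 0.28; Igfbp5 2.53, 2.21 to 2.89). In the cartilage matrix list 1 of 18 genes was past 1.5-fold, Matn1 at 0.595 (0.531 to 0.667), and the median was −0.08. Beside these stood haemoglobin genes with a median of −2.14, neutrophil granule genes with −2.59, MHC class II genes with −1.03 and mitochondrially encoded genes with 0.18.

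**Figure D3:**
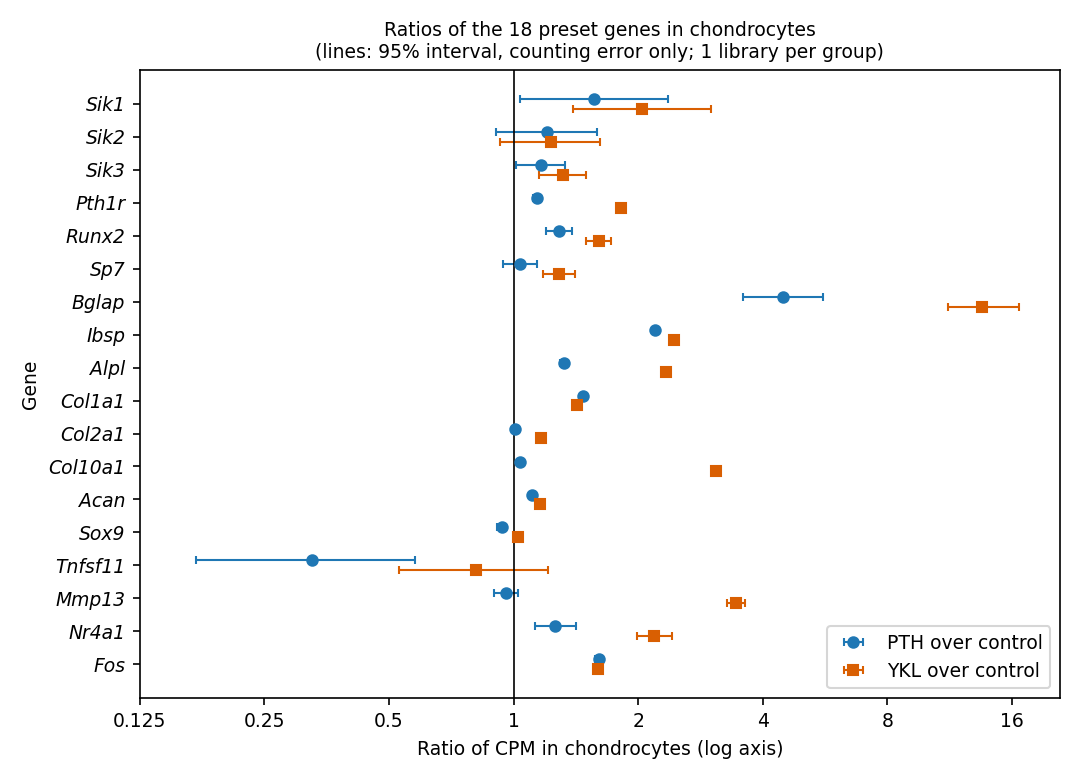
Ratio of CPM in chondrocytes (x axis, log scale) of the PTH (circles) and YKL (squares) libraries over the control for the 18 genes fixed in advance (y axis); lines are 95% intervals for counting error only. Bglap stood at 4.47 for PTH and 13.6 for YKL, and Col10a1 at 1.04 and 3.09.

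YKL and PTH were then compared directly, a ratio that does not use the control library. In chondrocytes 8 of 11 hypertrophic genes were at least 1.5-fold higher in the YKL than in the PTH library and none lower, with a median of 0.82; with clusters weighted equally the count was 4. Mmp13 was 3.59-fold higher (3.38 to 3.82), Col10a1 2.98-fold (2.95 to 3.02) and Ihh 1.97-fold (1.89 to 2.05). Among 18 osteoblast genes 9 were higher and 1 lower (median 0.47), with Bglap at 3.04 (2.65 to 3.50), Ifitm5 at 6.25 (4.08 to 9.95) and Dmp1, the matrix protein of late osteoblasts and osteocytes, at 20.8 (9.82 to 52.5), although Dmp1 was at 0.172 and Ifitm5 at 2.33 with doublets kept. The cAMP, CREB and CRTC list had 8 of 20 genes higher and a median of 0.36, with Nr4a1 at 1.74 (1.56 to 1.94) and the prostaglandin synthase gene Ptgs2 at 2.08 (1.97 to 2.20), while Fos was at 0.997 (0.979 to 1.02) and Sik1 at 1.31 (0.870 to 1.97). All 18 measured G2 and M phase genes were at least 1.5-fold lower in the YKL chondrocytes (median −2.81; −0.10 with clusters weighted equally), as were 6 of 10 IGF genes (median −1.03), with Igfbp5 at 0.201 (0.161 to 0.249). Nrn1 (neuritin), at 3.37 (2.99 to 3.82), was among the 3 genes that stood highest, and Tnmd at 0.00764 (0.00329 to 0.0151), Thbs4 at 0.0267 (0.0160 to 0.0420) and Sfrp5 at 0.0665 (0.0510 to 0.0854) stood lowest. Markers of other cells differed here too. Fibroblast markers were at least 1.5-fold lower in 7 of 11 (median −0.79) and skeletal muscle markers in 5 of 5 (−2.18), while erythroid markers were higher in 4 of 4 (1.38).

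**Figure D4:**
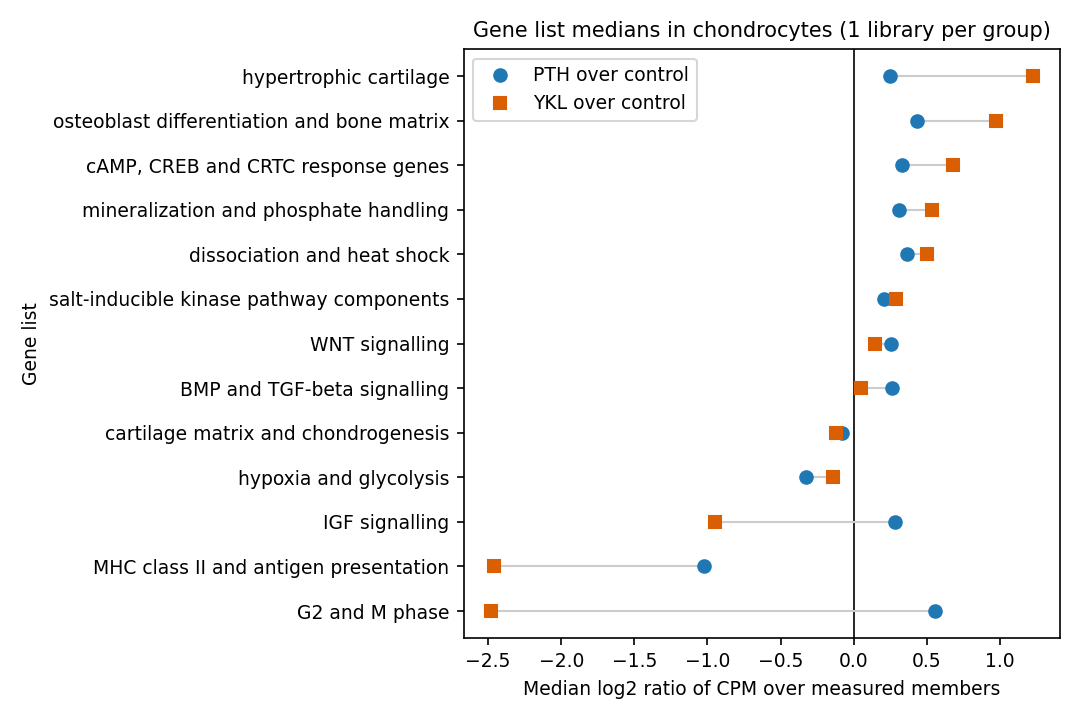
Median log2 ratio of CPM over the measured members of each gene list (x axis) in chondrocytes of the PTH (circles) and YKL (squares) libraries over the control; y axis, gene lists ordered by the YKL value. The hypertrophic list stood at 0.25 for PTH and 1.22 for YKL, and the G2 and M phase list at 0.55 and −2.48.

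Across 11426 genes, the log2 ratios of PTH and of YKL over control in chondrocytes had a Pearson correlation of 0.356 and a Spearman correlation of 0.408. Genes are not independent replicates, and both ratios share the control library: unchanged libraries drawn from the control 100 times gave mean correlations of 0.352 and 0.311. The covariance was 0.0770 against 0.0118 in the unchanged draws, a difference of 0.0652. In endothelial cells (5006 genes) the Pearson and Spearman correlations were 0.640 and 0.445 against 0.452 and 0.428 in unchanged draws, and the covariance was 0.168 against 0.0289, a difference of 0.139. The single control library cannot be split between the ratios, so the share of the excess due to it is unknown. The unchanged draws also hold no differences in RNA of other cells. In endothelial cells neutrophil granule genes had medians of −6.72 for PTH and −5.99 for YKL, and haemoglobin genes −3.68 and −3.18. The excess is therefore no measure of likeness of the treatments alone.

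In endothelial cells the PTH library stood apart by interferon response genes. Of 13 measured, 8 were at least 1.5-fold higher than in the control and none lower (median 0.89), with the antiviral genes Ifit1 at 5.18 (3.10 to 9.28), Ifit2 at 15.8 (4.19 to 133), Ifit3 at 4.19 (2.35 to 8.12) and Rsad2 at 2.71 (1.63 to 4.77). The count was 1 of 5 with a minimum of 200 UMIs and 3 of 5 in thinned cells. G2 and M phase genes were lower, 11 of 14 at least 1.5-fold (median −0.99; −0.25 with each cell weighted equally), with Ube2c at 0.215 (0.145 to 0.313). The cAMP list had 4 of 14 genes higher and 1 lower (median 0.27), with Fos at 2.22 (2.01 to 2.46) and the transcription factor gene Cebpb at 0.354 (0.259 to 0.481). Dissociation genes had a median of 0.28, and without the shared members the cAMP median was 0.17. Highest by the naming rule, beside Ifit1, were the metallothionein gene Mt1 at 3.52 (2.59 to 4.87) and Ecrg4 at 2.96 (2.21 to 4.03). The lowest were genes of myeloid cells, namely Il1b at 0.00609 (0.000732 to 0.0224), Cxcl2 at 0.0126 (0.00257 to 0.0377) and the lysozyme gene Lyz2 at 0.0661 (0.0436 to 0.0969), beside 4 of 5 inflammatory genes lower (median −2.13), neutrophil granule genes with a median of −6.72 (Ngp, at 0 UMIs, held at its floor) and haemoglobin genes with −3.68. Il1b, Cxcl2 and Lyz2 also lead a neutrophil-like cluster, and neutrophil-like cells were 14.8% of the control and 1.10% of the PTH cells. RNA of those cells cannot be told apart from expression of these genes by endothelial cells. Genes of cartilage were counted in the endothelial cells as well: 12 of 14 cartilage matrix genes were at least 1.5-fold higher in the PTH library (median 1.26). That median was −1.82 with doublets kept and −1.59 with the doublet score limit of 0.25 in all libraries. Ecrg4 and Mt1 likewise stood at 0.268 and 0.892 with doublets kept, and Ecrg4 at 0.876 with the score limit. Scrublet had marked 46 control and 1 PTH barcodes, so the direction of these values depended on a doublet removal that was uneven between the libraries. Clusters 11 and 16 formed this class, with 173 and 112 of 285 PTH cells, 98 and 60 of 158 control cells, and 30 and 21 of 51 YKL cells.

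Endothelial cells of the YKL library, 51 in all, differed from control in cAMP response genes, of which 6 of 11 were at least 1.5-fold higher and 1 lower (median 0.68), with the AP-1 gene Fosb at 3.37 (2.39 to 4.79), Atf3 at 2.99 (2.33 to 3.85) and Fos at 2.20 (1.94 to 2.51). Without the members shared with the dissociation list the median was 0.40, and in that list 4 of 14 genes were higher (median 0.13). G2 and M phase genes had 6 of 13 higher (median 0.46; Cenpa 3.31, 2.35 to 4.70) and interferon genes 3 of 6 lower (median −0.63; Iigp1 0.366, 0.230 to 0.562). Ptn (pleiotrophin) at 24.0 (12.6 to 51.5), the protease inhibitor gene Slpi at 11.7 (6.09 to 24.7) and the cartilage-derived protein gene Mia at 10.7 (5.14 to 24.9) stood highest by the naming rule, although Slpi was at 2.14 with classes from marker scores. Il1b had 0 UMIs in YKL against 167 in control cells, at least 25.5-fold lower at the floor of 3 counts (exact upper limit of the ratio 0.0488), and Lyz2 was at 0.00945 (0.000238 to 0.0532) from 1 UMI. Il1b and Lyz2 also lead a neutrophil-like cluster, and neutrophil-like cells were 14.8% of the control and 2.65% of the YKL cells. RNA of those cells cannot be told apart from expression by endothelial cells. A row for Ccl21a, a lymphatic chemokine whose gene has near-identical copies and so is uncertain, had 0 UMIs against 165, at least 25.2-fold lower (exact upper limit 0.0494). Cartilage matrix genes were higher here too, 11 of 12 at least 1.5-fold (median 1.40; −0.88 with doublets kept), and neutrophil granule and haemoglobin genes had medians of −5.99 and −3.18, the former with genes at 0 UMIs held at the floor. Set directly against PTH, 11 of 13 interferon genes were at least 1.5-fold lower in the YKL endothelial cells (median −1.18) and 14 of 14 G2 and M phase genes higher (median 1.55; 0.34 with each cell weighted equally). Ptn at 12.1 (8.33 to 17.9) and the placental growth factor gene Pgf at 0.0346 (0.000869 to 0.196), from 1 YKL UMI, were among the genes farthest from 1.

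Osteoblast-lineage, macrophage-like and fibroblast-like cells reached 50 only in the PTH and control libraries, and their genes were named after cell counts had been seen. Pericyte-like cells also did (62 and 78 cells) but were not among the classes chosen for naming genes. In osteoblast-lineage cells (62 PTH and 50 control cells, all of cluster 17) 7 of 16 osteoblast genes were at least 1.5-fold higher and 1 lower (median 0.53), some of them markers by which the class was named. Dmp1 was at 6.39 (3.47 to 13.1), Bglap at 6.05 (2.46 to 19.3), Pth1r at 1.58 (1.39 to 1.79) and the osteoblast transcription factor Sp7 at 1.66 (1.20 to 2.34), while Ifitm5 was at 0.455 (0.362 to 0.571). G2 and M phase genes were higher, 9 of 10 at least 1.5-fold (median 1.82), with the centromere genes Cenpf at 15.9 (6.05 to 59.1) and Cenpa at 7.38 (3.63 to 17.5) and Ube2c at 7.95 (4.22 to 16.9). Glycolysis and hypoxia genes were lower, 12 of 13 at least 1.5-fold (median −1.11), with phosphoglycerate kinase Pgk1 at 0.339 (0.293 to 0.391), Gapdh at 0.464 (0.428 to 0.503) and Vegfa at 0.318 (0.209 to 0.478). IGF genes were lower in 4 of 8 (median −0.64; −1.36 with a minimum of 10 UMIs), with Igfbp5 at 0.123 (0.0987 to 0.153). The chemokine gene Cxcl12 at 0.104 (0.0537 to 0.186) and Ucma at 0.103 (0.0486 to 0.200) were also among the lowest. Markers of other cells in this class included 2 of 4 measured osteoclast genes at least 1.5-fold higher (median 1.56; 0.94 with each cell weighted equally), and 1 of 3 pericyte genes higher and 2 lower (median −3.33). Most other clusterings gave no osteoblast class; where each cell took the class of its highest marker score, Ucma was at 1.83.

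In macrophage-like cells of the PTH library (78, against 128 in the control) 9 of 10 measured osteoclast genes were at least 1.5-fold higher, with a median of 2.06. The protease genes Mmp9 and Ctsk, which osteoclasts use to degrade bone matrix, were at 14.9 (12.2 to 18.5) and 5.55 (5.24 to 5.89), the fusion-related gene Ocstamp at 9.69 (6.14 to 16) and the integrin gene Itgb3 at 10.3 (4.42 to 29.2). Carbonic anhydrase Car2, which acidifies the resorption site, was at 7.85 (5.51 to 11.5), Mt3 at 9.47 (7.16 to 12.7) and Cyp2s1 at 36.6 (9.73 to 309.0), from 63 and 2 UMIs. Lowest were the chemokine genes Cxcl3, at 0 against 266 UMIs or at least 76.3-fold lower at the floor of 3 counts (exact upper limit of the ratio 0.0162), and Ccl5 at 0.00512 (0.000129 to 0.0288) from 1 UMI, and the macrophage elastase gene Mmp12 at 0.0203 (0.0113 to 0.0336). Ccl5 also leads the T-like or NK-like cluster, so RNA of those cells cannot be told apart from expression by the macrophages. Repair macrophage genes had 1 of 6 higher (Folr2 3.16, 2.39 to 4.21) and 3 lower (median −0.37, or 0.39 with a minimum of 10 UMIs; Gpnmb 0.188, 0.156 to 0.225), and inflammatory genes 4 of 12 higher and 6 lower (median −0.56, or 0.06 by marker scores; Ccl7 5.65, 3.55 to 9.40). All genes of this class had a median of 0.22, and after rescaling to a median of 0 the osteoclast median was 1.85. Among all genes past 1.5-fold, 72.8% were higher in the PTH macrophages, and 46.2% after that rescaling. With classes from marker scores, 2 of 6 osteoclast genes were past 1.5-fold and Ctsk was at 1.17, and in the clusters as reported 8 of the 78 PTH cells held 75.5% of the UMIs of 6 osteoclast genes. In the control 13 of the 128 cells held 85.9%. Beside these, 4 of 4 haemoglobin genes (median −2.35) and 8 of 8 cartilage matrix genes (median −1.56; 0.76 with classes from marker scores) were at least 1.5-fold lower in this class. In cells thinned to 2000 UMIs, Ctsk was seen in 33.3% of PTH and 14.5% of control macrophages (42.3% and 27.3% unthinned) and in 2 of 253 and 1 of 142 endothelial cells. The osteoclast gene Acp5 was seen in 39.7% of PTH and 37.9% of control macrophages (53.8% and 53.9% unthinned). The macrophages had median depths of 9196.5 and 7052.5 UMIs, and 0 and 4 were too shallow.

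Fibroblast-like cells (290 PTH and 116 control cells, all of cluster 9) had 8 of 12 interferon genes at least 1.5-fold higher in the PTH library (median 1.87), with Ifit1 at 14.5 (6.55 to 39.9), Ifit3 at 13.1 (4.38 to 64.7) and the ubiquitin-like modifier gene Isg15 at 5.63 (3.62 to 9.22). The monocyte-attracting chemokine genes Ccl2 at 24.6 (8.29 to 120.2) and Ccl7 at 15.0 (7.51 to 35.0), and the adhesion gene Chl1 at 16.7 (8.36 to 38.9), stood highest. Among 21 matrix remodelling genes 4 were higher and none lower (median 0.14), with the matrix protease genes Mmp3 at 8.87 (6.0 to 13.7) and Adamts5 at 2.56 (2.25 to 2.93). Cartilage matrix genes were lower in 10 of 12 (median −2.52), with Col2a1 at 0.0983 (0.0868 to 0.111), and haemoglobin genes in 4 of 4 (median −1.66). Ccl5 at 0.00401 (0.000100 to 0.0229) from 1 UMI, Lyz2 at 0.115 (0.0814 to 0.159) and Ltbp2 at 0.135 (0.0879 to 0.204) stood lowest. Ccl5 also leads the T-like or NK-like cluster (2.72% of control and 0.523% of PTH cells). Lyz2 is a leading gene of the neutrophil-like clusters (14.8% and 1.10%). Haemoglobin genes made up 29.6% of all control and 12.8% of all PTH UMIs. For Ccl5 and Lyz2, expression by the fibroblast-like cells cannot be told apart from RNA of those other cells. Chondrocyte-like cells were 53.7% of the control and 37.8% of the PTH cells. Whether the cartilage matrix genes in this class came from chondrocyte RNA was not tested. With the tendon-led cluster counted in this class, the interferon median was 0.95 and the cartilage matrix median −0.90.

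The genes that carry these comparisons lie as follows in the GRCm38 (mm10) annotation of protein-coding genes. Col10a1 (ENSMUSG00000039462) spans chromosome 10 from 34389981 to 34397085, Ihh (ENSMUSG00000006538) chromosome 1 from 74945315 to 74951672, and Mmp13 (ENSMUSG00000050578) chromosome 9 from 7272514 to 7283331. Bglap (ENSMUSG00000074483) spans chromosome 3 from 88383501 to 88384464, Ibsp (ENSMUSG00000029306) chromosome 5 from 104299171 to 104311469, and Dmp1 (ENSMUSG00000029307) chromosome 5 from 104202613 to 104214102. Sik1 (ENSMUSG00000024042) spans chromosome 17 from 31844250 to 31855804, Sik2 (ENSMUSG00000037112) chromosome 9 from 50892801 to 51009073 and Sik3 (ENSMUSG00000034135) chromosome 9 from 46012820 to 46224194. Pth1r (ENSMUSG00000032492) lies on chromosome 9 from 110722085 to 110747145, Ctsk (ENSMUSG00000028111) on chromosome 3 from 95499256 to 95509362 and Ifit1 (ENSMUSG00000034459) on chromosome 19 from 34640871 to 34650009.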

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

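Of the tests below, those of tendon collected with the callus and of Thbs4 in macrophages were chosen only after the result was seen. In the PTH library 44.5% (43.2 to 45.9) of barcodes were above 10% mitochondrial UMIs and stood outside every comparison, against 17.6% in the control and 18.5% in the YKL library. Among barcodes with at least 500 genes it was 21.5%, 14.3% and 11.8% in the same order. Unnamed cluster 18, which carries muscle and endothelial markers, held 2.82% of the PTH cells, 2.98% of the YKL cells and 1.51% of the control cells. The tendon-led cluster 21 held 12.6% of the PTH cells and 0.0688% of the control cells.

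Some gene lists went opposite ways in different classes under the same comparison, and these differences between classes were not tested. G2 and M phase genes had a median log2 ratio of 1.82 in osteoblast-lineage cells and −0.99 in endothelial cells for PTH against control, the latter −0.25 with mean CPM per cell. The same list had a median of 1.55 in endothelial cells and −2.81 in chondrocytes for YKL against PTH, but 0.34 in endothelial cells with mean CPM per cell and −0.10 in chondrocytes with clusters weighted equally. Cartilage matrix genes had a median of 1.26 in endothelial cells, −2.52 in fibroblast-like cells and −1.56 in macrophage-like cells for PTH against control. The endothelial value was −1.82 with doublets kept, −0.95 with a minimum of 1000 genes and −1.59 with a limit on doublet scores, the fibroblast value −0.90 with the tendon-led cluster counted in, and the macrophage value 0.76 by marker scores. Hypertrophic genes had a median of 1.55 in endothelial cells and −0.85 in fibroblast-like cells for the same comparison, and the endothelial value was −0.14 with doublets kept and −0.27 with the doublet score limit, and the fibroblast value −0.03 with the tendon-led cluster counted in.

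Thbs4 was 4.02-fold higher in the PTH than in the control chondrocytes, and the PTH library alone held more than 2 cells of a tendon-led cluster that carries Thbs4 at 3797 CPM. Free RNA of those cells would bring it to every class, and endothelial cells of the PTH library held 29.5% (20.5 to 41.3) of the level in its chondrocytes, 15.7 against 53.3 CPM. In cells thinned to 2000 UMIs, Thbs4 was seen in 6 of 78 PTH macrophages (7.69%, 2.88 to 16) and 0 of 124 control macrophages, beside 5.97% (4.33 to 7.98) of the PTH chondrocytes and 2.77% (1.12 to 5.62) of the PTH endothelial cells. Part of the difference may therefore be free RNA, but the endothelial value lies between the levels that would have decided it, and free RNA cannot be told apart from expression by the chondrocytes. Tendon or ligament collected with the callus in 1 library could also account for a cluster of 12.6% of its cells, which cannot be told apart from an effect of PTH with 1 library per group.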

How the results depend on the processing

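Alternatives with equal cluster weights, a depth window, a doublet score limit, mixed clusters kept, the tendon-led cluster counted with fibroblasts, or no dissociation genes were chosen after the data were seen. No paired analysis was possible because each group had 1 library and the libraries share no animals or numbers that would pair them. Of 189 shares of cell classes 145 held within their intervals, 44 moved and 0 reversed, and of 82 list counts 67 held and 15 moved. A list median counted as reversed only where it was at least 1.5-fold and changed sign, and a ratio only where it was at least 1.5-fold with an interval clear of 1 and changed direction. Of 650 list medians for PTH against control 476 held, 168 moved and 6 reversed, and 39 changed sign at any size. For YKL against control 308 of 401 held, 91 moved and 2 reversed, and 12 changed sign, and for YKL against PTH 71 of 94 held, 23 moved and 0 changed sign. Ratios of named genes reversed in 22 of 2203 cases for PTH against control, 11 of 1298 for YKL against control and 3 of 659 for YKL against PTH, and changed direction at any size in 59, 22 and 20. All 24 values of library quality held, and of 33 similarities 17 held and 16 moved. Only genes and lists that the text names were followed, and the osteoblast class was found only in the clusters as reported and by marker scores. Cells of the YKL library other than chondrocytes were few, and ratios of genes with few UMIs have wide intervals at this depth.

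The chondrocyte share in the control was 43.2% with a minimum of 200 genes, 61.9% with 1000 genes, 51.4% with a mitochondrial maximum of 20%, 55.7% at resolution 0.4, 56.4% with 4000 variable genes, 56.9% with each library clustered alone, 48.5% by marker scores and 57.7% with mixed clusters kept. In the PTH library it was 32.2% with 200 genes, 41.1% at resolution 0.4, 41.6% with 4000 variable genes and 31.8% by marker scores. In the YKL library it was 55.8% with 200 genes, 74.7% with 4000 variable genes and 60.4% by marker scores.

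Counts of list members past 1.5-fold moved as well. Thinning to 2000 UMIs, where fewer genes were measured, gave 4 of 12 cAMP genes higher in PTH chondrocytes, 3 of 12 osteoblast genes higher and 3 of 3 G2 and M phase genes lower in YKL chondrocytes, 3 of 5 interferon genes in PTH endothelial cells and 3 of 5 osteoclast genes in PTH macrophages. A minimum of 200 UMIs also left fewer genes, and gave 7 of 13 osteoblast genes and 12 of 12 G2 and M phase genes in YKL chondrocytes, 1 of 5 interferon genes, 7 of 7 hypoxia genes in PTH osteoblasts, and a Pearson correlation of 0.441. For osteoblast genes higher in PTH chondrocytes, the count was 9 of 19 with a minimum of 10 UMIs, 9 of 17 with doublets kept, 9 of 17 with 1000 genes, 11 of 18 with a mitochondrial maximum of 5%, 2 of 15 with clusters weighted equally and 2 of 13 in cells of 10000 to 20000 UMIs. Of the cAMP genes in PTH chondrocytes 4 of 17 were higher without dissociation genes and 3 of 21 with a mitochondrial maximum of 5%. With clusters weighted equally, 3 of 11 hypertrophic genes were higher and 3 of 7 G2 and M phase genes lower in YKL chondrocytes, and 4 of 11 hypertrophic genes were higher for YKL against PTH. By marker scores 2 of 6 osteoclast genes were higher. Except where fewer genes were measured, the cause was not tested.

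Among smaller medians that changed sign, for PTH against control in chondrocytes G2 and M phase genes were at −0.58 and hypertrophic genes at −0.01 with clusters weighted equally, and IGF genes at −0.08, WNT genes at −0.13 and cAMP genes outside the dissociation list at −0.06 in thinned cells. In thinned endothelial cells the last list was at −0.46, and matrix remodelling in thinned fibroblasts at −0.01. Repair genes in macrophages were at 0.39 with a minimum of 10 UMIs and inflammatory genes at 0.06 by marker scores, and in osteoblasts BMP genes were at 0.26 with a minimum of 200 UMIs and WNT genes at 0.06 by marker scores. For YKL against control in chondrocytes WNT genes were at −0.10 by marker scores cartilage matrix genes at 0.01 with clusters weighted equally, and lipid genes at 0.21 with a minimum of 10 UMIs.

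These values of at least 1.5-fold reversed, and the cause was not tested. With mean CPM per cell, the inflammatory median was 0.35 and H2-Aa was at 1.75 in YKL against control chondrocytes and Gbp2 at 1.28 in endothelial cells. With doublets kept, endothelial cells of PTH against control had a cartilage matrix median of −1.82, a hypertrophic median of −0.14, Acan at 0.378, Col2a1 at 0.282, Ecrg4 at 0.268, Mt1 at 0.892, Pth1r at 0.910 and Snorc at 0.347. Those of YKL against control had a median of −0.88, Acan at 0.523 and Col2a1 at 0.542, and Dmp1 was at 0.172 in YKL against PTH chondrocytes. With a minimum of 1000 genes, the PTH endothelial cells had a median of −0.95, Acan at 0.516, Col2a1 at 0.479, Mt1 at 0.981 and Snorc at 0.375, while Igfbp3 was at 1.04 in YKL against control and Dmp1 at 0.172 in YKL against PTH chondrocytes. With a mitochondrial maximum of 5%, Mmp13 was at 0.442 in PTH fibroblasts. By marker scores, PTH against control gave a cartilage matrix median of 0.76 and Acan at 1.03 in macrophages, and Col10a1 at 0.417 and Ucma at 1.83 in osteoblasts. With doublet scores limited to 0.25, the PTH endothelial cells had a cartilage matrix median of −1.59, a hypertrophic median of −0.27, Acan at 0.348, Col2a1 at 0.268, Ecrg4 at 0.876, Pth1r at 0.830 and Snorc at 0.333, and Ecrg4 was at 2.70 in YKL against PTH. With the tendon-led cluster counted in, Acan was at 1.31 in PTH fibroblasts. With clusters weighted equally, YKL against control chondrocytes had Cnmd at 1.00, Col10a1 at 0.833, Ibsp at 0.901, Mmp13 at 0.923, Rrm2 at 1.61 and Spp1 at 0.902. In cells of 10000 to 20000 UMIs, Cd74 was at 2.01 and Sfrp2 at 0.837 in PTH against control chondrocytes.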

Other observations

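Of the tests below, that of treatment as the source of the hypertrophic pattern, and for osteoclast genes the ratio of median cells, the comparison with the control's top cells and the CPM limits, were chosen only after the result was seen. Matrix remodelling genes of the YKL chondrocytes went both ways against control, with 3 of 20 at least 1.5-fold higher and 4 lower (median −0.29). Timp3, a protease inhibitor bound to the matrix, was at 3.11 (2.95 to 3.27), while the matricellular genes Postn and Thbs2 were at 0.337 (0.323 to 0.352) and 0.317 (0.275 to 0.365). S phase genes were lower in 6 of 18 (median −0.42), with the helicase gene Hells at 0.353 (0.201 to 0.587). Angiogenesis genes had 3 of 6 higher and 1 lower (median 0.55; 0.05 to 0.67 over the alternatives), osteoclast-inducing ligands and decoy 1 of 6 higher and 1 lower (−0.16; −0.63 to 0.17), and lipid genes 3 of 6 lower and 1 higher (−0.55; −0.70 to 0.21). Inflammatory genes were lower in 4 of 7 (median −1.81; 0.35 with mean CPM per cell). Interferon genes had a median of −0.24 (−1.03 to 0.14 over the alternatives), unfolded protein response genes −0.10 (−0.14 to −0.01) and osteoclast genes −0.22 (−0.71 to 0.50). For PTH against control the medians, with their ranges over the alternatives, were 0.03 for matrix remodelling (−0.11 to 0.32), 0.15 for S phase (0.01 to 0.22), 0.18 for angiogenesis (0.01 to 0.89), 0.07 for ligands (−0.20 to 0.10) and −0.03 for lipid genes (−0.54 to 0.67). Inflammatory genes stood at −0.31 (−0.55 to 0.05), interferon at 0.39 (0.04 to 0.55), unfolded protein response at 0.07 (0.00 to 0.09) and osteoclast genes at 0.09 (−0.14 to 0.46).

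In macrophage-like cells of the PTH library lipid handling genes were at least 1.5-fold lower than in the control in 5 of 6 (median −0.95), with the fatty acid transporter gene Cd36 at 0.161 (0.101 to 0.245), the lipase gene Lpl at 0.517 (0.454 to 0.587) and the apolipoprotein gene Apoe at 0.621 (0.597 to 0.645). MHC class II genes were lower in 2 of 8 (median −0.52; −0.02 with mean CPM per cell), with H2-Aa at 0.570 (0.534 to 0.608). In osteoblast-lineage cells BMP and TGF-beta genes were at least 1.5-fold higher in 3 of 14 and lower in 7 (median −0.55; 0.26 with a minimum of 200 UMIs and 0.19 by marker scores), and WNT genes had a median of −0.57 (0.06 by marker scores).

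Hypertrophic genes were higher in the YKL than in the control chondrocytes, with a median of 1.22. Depth alone is argued against, since the median was 1.03 (0.99 to 1.07) among 850 control and 46 YKL chondrocytes of 10000 to 20000 UMIs. A larger share of hypertrophic cells is a candidate explanation for much of it: with 6 clusters formed without bone and hypertrophic genes weighted equally, the median was 0.49 (0.37 to 0.56), and within them it ran from −0.68 to 0.98. These clusters held 900 of 1562 control and 412 of 428 YKL chondrocytes, and new clusters 3 and 6 had 13 YKL cells each. The fall in the median may therefore also reflect the control cells left out, and its interval covers counting error only. The difference that remains may be one within cells, a finer mixture of cells or free RNA, which these clusters do not separate. Thinned Col10a1 was detected in 34.0% of YKL and 11.3% of control endothelial cells, but Ihh in 0 of 47 and 0 of 142. Whether treatment gave the larger share cannot be told apart from differences between animals, healing stage or the piece dissected, since there was 1 library per group.

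Osteoclast genes were higher in the PTH than in the control macrophages, 4.72-fold (4.55 to 4.90) for 6 of them summed. The median cells stood at 293 CPM in the PTH and 249 CPM in the control class, a ratio of 1.18 (0.424 to 3.19 over resampled cells). The interval of the summed ratio counts UMIs and not cells, so the 2 ranges are unlike. They cannot exclude higher expression by most of the PTH cells. Free osteoclast RNA in the PTH droplets is argued against, since endothelial cells held 0.1255% (0.0896 to 0.171) of the macrophage level. Few cells held most of these UMIs in both libraries, 75.5% (74.8 to 76.2) in 8 of 78 PTH cells. In the control it was 85.9% in 13 of 128 cells. Without these cells the ratio was 8.95 (8.15 to 9.85), but the cut was uneven. At least 10000 CPM was reached by 13 PTH and 2 control cells, so some such PTH cells stayed in. That ratio is therefore no sign of a rise in many cells. Among cells under 5000, 10000 and 20000 CPM the ratios were 0.956 (0.535 to 1.53), 0.840 (0.365 to 1.73) and 2.0 (0.712 to 3.99). A limit on the same 6 genes pulls these ratios towards 1, so they cannot decide. Each range also spans 1, and a few osteoclast-like cells cannot be told apart from a smaller rise in many cells. Cells with at least 10000 CPM made up 16.7% (9.18 to 26.8) of the PTH and 1.56% (0.190 to 5.53) of the control class, and at 5000 CPM 19.2% (11.2 to 29.7) and 7.03% (3.27 to 12.9), and an effect of PTH stays open with 1 library per group.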
